A study of Homo sapiens with 2 samples.

How the data were processed

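Total RNA from SW620 cells, an established human colon carcinoma line, was measured on 2 one-colour arrays. One array held RNA of cells with a control lentivirus and the other RNA of cells made to express CDR1AS, so each group was 1 array. Per the labels, the RNA was extracted with Trizol, amplified with amino allyl nucleotides, coupled to Cy5 and fragmented by Toray's protocol. Per the file headers, the deposited spot intensity is the median brightness of a spot at 635 nm, read at 3 scanner gains with fitted lines between the gains. How the gains were joined into 1 intensity is not given in the sources used here. Each array had 27456 positions, of which 384 were blank spots and 2412 were empty. Of 24460 gene probes, 1 was left out for a quality flag and 24459 were kept.

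The deposited spot intensity was not corrected for background. The local background column of the authors' spot files rose with the spot's own brightness (Pearson's r across spots on the log scale 0.977 on the control array and 0.942 on the CDR1AS array, where spots are not independent replicates). Among the brightest spots (2353 on the control array and 2432 on the CDR1AS array), its rise over its level at blank spots was set against the spot's intensity over the blanks. The median share was 68.6% on the control array and 37.3% on the CDR1AS array. The local background column was therefore not used as a background in the main setting. The main values were made with limma 3.58.1 in R 4.3.3, by normexp correction without the local background and with an offset of 50, quantile normalization over the 2 arrays and log2. An offset of 50 is large beside the net intensity of a typical spot, whose median brightness was 103 on the control array over blanks at 65.9. Folds of dim genes are therefore compressed towards 1 on this scale, and deposited values are given beside them where this matters.

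The deposited value table of the series was set against the spot files to find what it holds, since its scale and direction are not given in the sources used here. Each of its columns was a straight line of that array's intensity, with a largest residual of 0.0510 units for the control array and 0.0559 for the CDR1AS array. It held the spot intensity minus a trimmed mean of the blank spots, times 1 factor per array that placed both medians at 25, on a linear scale with no centring of genes. Values near the blank level were left empty there. No unknown in scale, centring or direction remained, and the table served as an alternative.

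A probe was above background where its spot exceeded the mean of the blank spots by more than 2 SD. The blanks averaged 65.9 ± 1.60 (SD, 384 spots) on the control array and 69.5 ± 1.30 on the CDR1AS array, which placed the limits at 69.1 and 72.1. A gene was represented by its brightest probe and kept where it was above background on at least 1 array. For a gene above background on 1 array only, the dim side was set to the higher of its own value and the lowest value among probes above background, and the fold is given as "at least". Probe genes came from the platform's annotation: 21706 probes had 1 symbol, 0 had several and 2753 had none. Of these, 21674 matched a gene of the RefSeq annotation of GRCh38.p14 by gene identifier, and 0 symbols changed. The genome build of the array's design is not given in the sources used here, so no coordinates are printed, and the annotation served for names and for which genes neighbour each other.

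With 1 array per group there is no replicate error, no test of a difference and no p-value, and the number of arrays limits the precision of every value. Genes at or past 2-fold were counted instead. For each of 30 gene lists, the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched on mean level in 20 bins. A list is said to stand apart where its percentile lay under 2.5 or over 97.5, which describes these 2 arrays and not the conditions. Lists, thresholds and the rule for naming genes were fixed before the data were examined. The rule took the 12 highest and 12 lowest ratios among genes above background on both arrays and in the upper range of mean level, and the 3 largest bounds each way among genes above background on 1 array. It also took all measured members of the CDR1 locus and of the CMTM family, 2 PD-1 ligands and 8 miR-7 targets, not all of which are reported here. Finally it took the 4 leading members of each other list that stood apart and any list member past 2-fold. The lists not described one by one in the results are named there with their values.

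The steps were tested on simulated data made from the real intensities of 24459 probes. Among genes raised by 1.5 on the log2 scale, 22 of 24 in the brighter part of the range were called at 2-fold and 0 of 26 in the dimmer part. Among those lowered by 1.5 the counts were 11 of 24 and 0 of 26. At a change of 2 they were 30 of 30 and 7 of 20 for genes raised, and 21 of 32 and 0 of 18 for genes lowered. None of 20231 probes left unchanged was called, which reflects a simulation with no difference between cultures. Of 100 simulated lists of 25 genes, 6 stood apart with no shift and 89 with a shift of 0.2.

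The alternatives were scaling to a common median, the deposited value table, loess normalization of the ratio, subtraction of the local background with a floor of 1, an offset of 16, no filter or a stricter filter on dim probes, the median of a gene's probes, other fold thresholds and random lists without matching. The stricter filter kept probes over 2 times the background limit on both arrays, so it also drops genes that are dim on 1 array only. Centring within array blocks and leaving out a shifted stretch of chromosome 2 were added after the data were seen. Lists and figures were computed with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3. A planned comparison of genes with and without miR-7 sites in the 3' UTR was not run, because transcript sequences were not used here.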

Results

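The series addressed which transcripts differ when CDR1AS is expressed in colon cancer cells. CDR1AS is a circular RNA from the CDR1 antisense locus that carries many binding sites for the microRNA miR-7. SW620 cells, a line from a lymph node metastasis of a colon carcinoma, carried either a control lentivirus (1 array) or expressed CDR1AS (1 array). Of 24459 gene probes, 20642 (84.4%) were above background on the control array and 21322 (87.2%) on the CDR1AS array. The median probe above background had 1.77 times the background limit on the control array and 1.75 times on the CDR1AS array, so most transcripts were measured close to the floor. Repeated positive-control spots within an array varied by an SD of 0.10 to 0.24 on the log2 scale (24 spots each). There were no replicate arrays, so every difference below is a difference between 2 arrays and has no replicate check.

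Among genes with a symbol, the CDR1AS array differed from the control array most in VIM and RGCC on the higher side and in UBD, ALB and chemokine genes on the lower side. UBD, a ubiquitin-like modifier induced by inflammatory cytokines, was 14.5-fold lower (log2 ratio −3.86), and the chemokine genes CCL2 (−2.96), CCL20 (−2.76) and CXCL8 (−2.39) were also among the 12 lowest. ALB, which encodes serum albumin, was 8.80-fold lower (−3.14), and its other probe gave −2.55. RGCC, a cell cycle regulator, was 9.71-fold higher (3.28). ANXA1, which encodes annexin A1, was 5.31-fold higher (2.41), and its other probe was past 2-fold as well. The brightest probe of VIM, the intermediate filament gene of mesenchymal cells, was 12.4-fold higher (3.64), but its other probes gave 0.02 and −0.07. The transcripts that each VIM probe detects are not known here.

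Altogether 16685 genes were measured, 15905 of them above background on both arrays, 628 on the CDR1AS array only and 152 on the control array only. At or past 2-fold, 126 genes were higher and 96 were lower on the CDR1AS array, together 1.33% of the genes measured. The log2 ratio had an SD of 0.29 over all genes, with quartiles of −0.10 and 0.09, and log2 levels correlated across genes between the arrays with Pearson's r = 0.984 (genes are not independent replicates). Where a gene had a pair of probes (2001 genes), the ratios of its probes correlated with r = 0.64 across genes. In 43 of these pairs at least 1 probe was past 2-fold, and in 10 both were, in the same direction. The count of genes past 2-fold depends on the setting: an offset of 16 gave 229 higher and 172 lower genes, and the deposited value table gave 674 and 444.

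**Figure D1:**
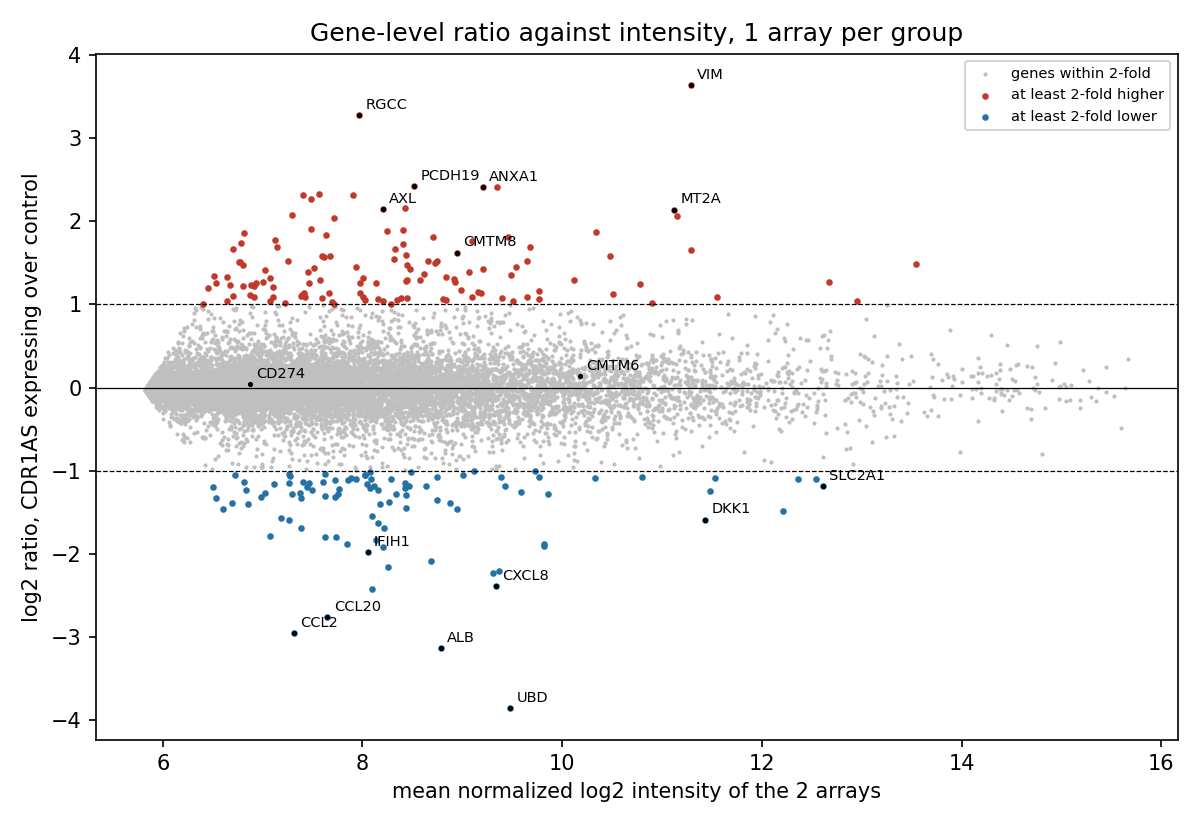
Log2 ratio of the CDR1AS array over the control array against the mean normalized log2 intensity of both arrays, 1 point per gene above background on both. Dashed lines mark 2-fold, red points are genes at least 2-fold higher, blue points genes at least 2-fold lower, and labelled black points are named genes. VIM (3.64) and UBD (−3.86) are the extremes, and CD274 (0.04) and CMTM6 (0.14) lie near 0.

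The other genes among the 12 highest were PCDH19 (2.43), a protocadherin whose other probe gave 1.39, PMAIP1 (2.41), which encodes the pro-apoptotic protein NOXA, SH3KBP1 (2.33), POPDC3 (2.32), IL1RAPL1 (2.32) and CRMP1 (2.27), a collapsin response mediator. PHGDH, the first enzyme of serine synthesis, was 4.48-fold higher (2.16, other probe 1.83), the receptor tyrosine kinase gene AXL was 4.42-fold higher (2.14) and the metallothionein gene MT2A 4.41-fold higher (2.14). The other genes among the 12 lowest were PHACTR3 (−2.42), the kallikrein gene KLK10 (−2.23), the Wnt inhibitor gene APCDD1 (−2.21), SMCO2 (−2.16), the collagen prolyl hydroxylase gene P3H2 (−2.09), the cytosolic RNA sensor gene IFIH1 (−1.98) and TMEM176A (−1.92). CCL20 and PHACTR3 were higher, not lower, after subtraction of the local background (0.82 and 2.47), and PMAIP1 (0.90), IL1RAPL1 (0.84) and CXCL8 (−0.98) were then within 2-fold. For genes near the floor on 1 array the offset compressed the fold: in the authors' deposited table CCL2 was 105-fold lower and RGCC 28.4-fold higher. The 105-fold is poorly determined, since the spot of CCL2 on the CDR1AS array was 73.2 against a background limit of 72.1. Its deposited value there was 1.7.

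Among genes above background on the CDR1AS array only, TNFRSF11B, which encodes osteoprotegerin, was at least 6.54-fold higher. The semaphorin and VEGF co-receptor gene NRP1 was at least 1.89-fold higher and the Wnt receptor gene FZD10 at least 1.73-fold higher. Among genes above background on the control array only, SIAE was at least 1.80-fold lower, the interferon-induced gene IFI44 at least 1.56-fold lower and SAMD13 at least 1.44-fold lower.

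No value is given here for circular CDR1AS itself, since none of the probes was matched to it. The measured probe of the locus was that of LINC00632, the host transcript from which CDR1AS is spliced, and its log2 ratio was −0.01. Its spots were close to background on both arrays, at 69.7 against a limit of 69.1 on the control array and 73.3 against 72.1 on the CDR1AS array. A probe for a linear host transcript does not report a circular RNA made from a vector, so this value does not check the labels of the arrays. CDR1 and other transcripts of the locus were not analysed here.

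The CMTM genes encode membrane proteins of the chemokine-like factor family, of which CMTM6 and CMTM4 keep PD-L1 at the cell surface. CMTM8 was 3.08-fold higher on the CDR1AS array (log2 ratio 1.62) and was the only one of the 9 measured members past 2-fold in the main setting. In the deposited value table CMTM8 was 3.74-fold higher, CMTM3 2.03-fold higher and CMTM2, close to background on both arrays, 2.31-fold lower. CMTM6 had a log2 ratio of 0.14, CMTM4 of −0.47, CMTM3 of 0.61 and CMTM7 of 0.32. The remaining members were CMTM1 (0.07), CMTM2 (−0.12), CMTM5 (−0.28) and CKLF (−0.30), and the other probes of CMTM1 gave −0.09 and −0.08. The median over the family was 0.07, at percentile 87.9 of random lists, so the family did not stand apart.

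The transcript of CD274, which encodes PD-L1, differed little between the arrays, with log2 ratios of 0.04 and −0.27 for its probes. It was dim, so its fold is compressed. The probe with 0.04 had a spot of 125 against a background limit of 69.1 on the control array. On the CDR1AS array it had 138 against 72.1. PDCD1LG2, which encodes PD-L2, had a log2 ratio of 0.03, close to background. Among 28 measured genes of the list fixed for the PD-1 ligands and regulators of PD-L1, 16 were above 0 and 12 below, and 0 were past 2-fold. The median was 0.03, at percentile 79.3. This list is not limited to surface regulators. It also held JAK1, JAK2, STAT3 and IRF1, which act on transcription, and the casein gene CSN1S1. The 15 measured immune checkpoint ligands had a median of −0.00, at percentile 52.3, with 0 past 2-fold. Protein at the cell surface was not analysed here.

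Genes reported as miR-7 targets in earlier studies did not stand apart on the CDR1AS array. Of 32 measured targets, 14 were above 0 and 18 below, with a median of −0.03 at percentile 19.2. Among the alternatives the percentile was lowest with scaling to a common median (3.51) and in the deposited value table (4.73). It was 27.4 with no filter on dim probes and highest after subtraction of the local background (66.5). The only one past 2-fold was PAX6, a transcription factor gene, at 2.23-fold higher (1.16). The insulin receptor substrate genes IRS1 (0.29) and IRS2 (0.17, other probe −0.07), the receptor gene IGF1R (0.19) and the NF-kB subunit gene RELA (0.05) stayed within 2-fold. EGFR was not above background on either array, and PAK1 was not analysed here. The 21 measured genes of the CDR1AS network and of circular RNA handling had a median of 0.02, at percentile 77.7. In the simulated data 0 of 26 dim genes raised by 1.5 on the log2 scale were called at 2-fold, and 7 of 20 raised by 2. Derepression of dim targets, even by such amounts, could therefore have been missed by that count.

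Interferon-stimulated genes had the lowest median of the lists on the CDR1AS array, and NF-kB targets and class I genes were lower too. Of 36 measured interferon-stimulated genes, 31 were below 0 and 4 were at least 2-fold lower, namely IFIH1 (−1.98), the tetherin gene BST2 (−1.63), IFI27 (−1.16) and the oligoadenylate synthetase gene OAS3 (−1.11, other probe 0.01). The list's median was −0.34, below all 10000 random lists. Of 22 NF-kB targets and inflammatory cytokines, 18 were below 0 and 6 at least 2-fold lower: CCL2, CCL20, CXCL8, the lymphotoxin gene LTB (−1.90), CXCL3 (−1.80) and CXCL2 (−1.32). Their median was −0.19, again below all random lists, but at percentile 6.45 with the stricter filter on dim probes, which left 8 of these genes. That filter asked for 2 times the background limit on both arrays. It dropped CCL2, CCL20, CXCL3 and CXCL2 because they were dim on the CDR1AS array, so the weaker call is partly built in. Of 18 genes of MHC class I antigen presentation, 17 were below 0 and 0 past 2-fold. The median was −0.27 (percentile 0.01), led by the immunoproteasome genes PSMB10 (−0.95), PSMB9 (−0.56) and PSMB8 (−0.53, other probe −0.11) and by TAPBPL (−0.65). The class I list did not stand apart after subtraction of the local background (percentile 36.9). The 10 measured leukocyte markers had a median of −0.03, at percentile 14.3.

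**Figure D2:**
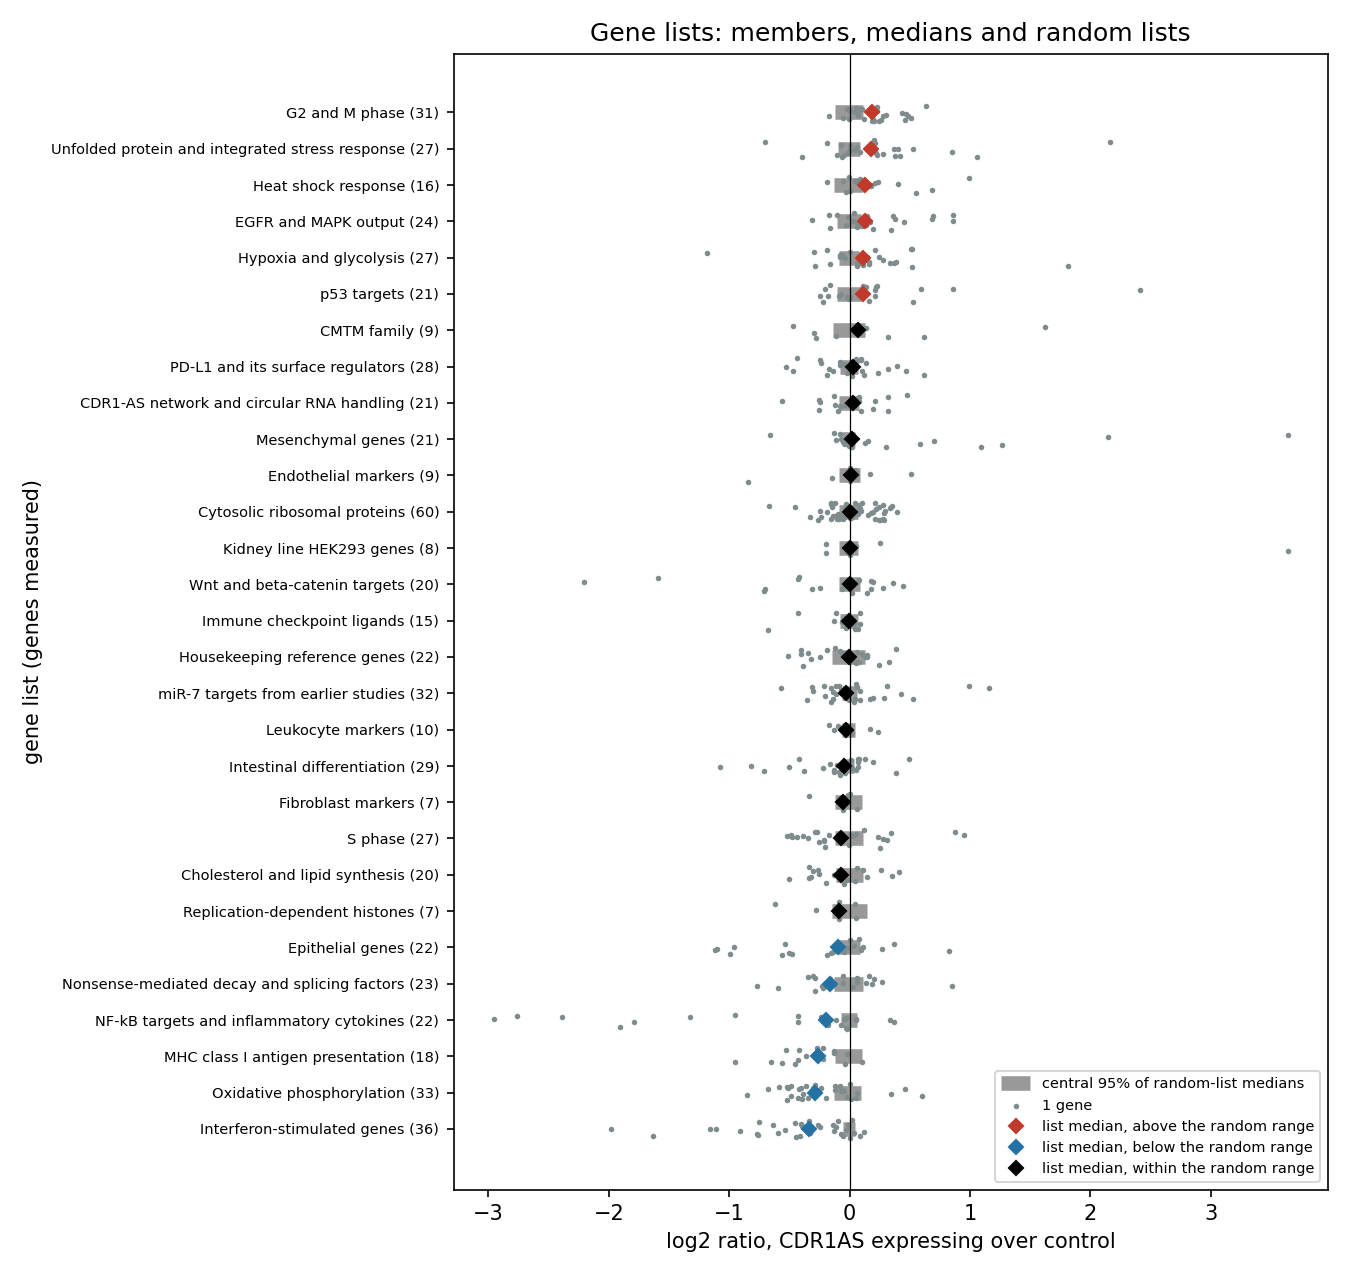
Log2 ratio of the CDR1AS array over the control array for each measured gene (grey points) of 29 lists, with the list median (diamond) and the central range of the medians of 10000 random lists matched on mean level (grey bar). Red and blue diamonds lie above and below the random range. Interferon-stimulated genes have the lowest median (−0.34) and G2 and M phase genes the highest (0.19).

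Epithelial and mesenchymal genes went both ways. Of 22 epithelial genes, 13 were below 0 and 9 above. The splicing regulator gene ESRP1 (−1.12) and the transcription factor gene ELF3 (−1.10) were at least 2-fold lower, followed by the protease gene ST14 (−0.99) and OVOL2 (−0.96, other probe 0.03), while the keratin gene KRT19, named here after its value was seen, had a log2 ratio of 0.83. The list's median was −0.09 at percentile 2.43, and this call held in 4 of 9 alternatives, and neither after local background subtraction (percentile 6.67) nor without the genes of a shifted stretch of chromosome 2 (percentile 2.65). Of 21 mesenchymal genes, 12 were above 0 and 9 below, and 4 were at least 2-fold higher: VIM by its brightest probe, AXL, the smooth muscle gene TAGLN (1.27, other probe 1.78) and the fibronectin gene FN1 (1.09). The transcription factor gene TWIST2, also named after its value was seen, was lowest (−0.66). The median of the 21 genes was 0.02 at percentile 88.1, so the list did not stand apart, but with the stricter filter on dim probes the 6 genes left had a median of 0.84, at percentile 100. The 7 measured fibroblast markers had a median of −0.055 (percentile 13.4), the 9 endothelial markers 0.02 (percentile 74.9) and the 8 genes typical of the kidney line HEK293, a common lentivirus packaging line, 0.00 (percentile 62.9), with VIM the only one of these genes past 2-fold.

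Genes of G2 and M phase and of stress responses had slightly higher medians on the CDR1AS array, but S phase genes did not. The calls of some stress lists depended on the setting. Of 31 G2 and M phase genes, 27 were above 0, with a median of 0.19 (percentile 99.97), led by TOP2A (0.64, other probe 0.31), HMMR (0.51), CDC20 (0.48) and BUB1 (0.47). The 27 S phase genes did not stand apart (median −0.07, percentile 13.0), but 25 of them did with the stricter filter on dim probes (−0.17, percentile 0.81), and they stood apart the other way after subtraction of the local background (0.42, percentile 99.6). Of 27 genes of the unfolded protein and integrated stress response, 18 were above 0 and 2 at least 2-fold higher, PHGDH and the transcription factor gene DDIT3 (1.05). The median was 0.17 (percentile 99.97), and DDIT4 (0.85) and SESN2 (0.52) followed. The 21 p53 targets had a median of 0.11 (percentile 98.6), led by PMAIP1, GADD45A (0.86) and AEN (0.59), with 12 above 0, but did not stand apart with scaling to a common median (0.07, percentile 90.4). The 16 heat shock genes had a median of 0.13 (percentile 98.4), with the chaperone genes HSP90AA1 (0.99), HSPH1 (0.68), DNAJB1 (0.55) and HSPD1 (0.40) leading. Both HSPD1 and HSPE1 of this list lie in a stretch of chromosome 2 whose genes were higher together, and without the genes of that stretch the list did not stand apart (median 0.07, percentile 92.2), nor did it with loess normalization or in the deposited value table (percentiles 96.5 and 96.8). The 24 genes of EGFR and MAPK output had a median of 0.13 (percentile 99.5) and 0 past 2-fold, with EMP1 (0.86), the phosphatase gene DUSP5 (0.86), ETV5 (0.69) and EPHA4 (0.68) leading. After subtraction of the local background the MAPK and p53 medians were below 0 (−0.0019 and −0.30), and the unfolded protein and heat shock lists no longer stood apart (percentiles 96.7 and 95.3).

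Genes of energy metabolism went in different directions. Of 33 measured oxidative phosphorylation genes, 26 were below 0, with a median of −0.28, below all 10000 random lists, and 0 past 2-fold. NDUFA6 (−0.85), NDUFB10 (−0.68) and NDUFA1 (−0.52) of complex I and COX7B (−0.59) of cytochrome c oxidase led the list, which did not stand apart after subtraction of the local background (percentile 69.1). The 27 hypoxia and glycolysis genes had a median of 0.11 (percentile 99.6), with 18 above 0. Within this list the glucose transporter genes were opposite, SLC2A3 at 3.52-fold higher (1.81) and SLC2A1 at 2.27-fold lower (−1.19). PFKFB4, P4HA1 and KDM3A had log2 ratios of 0.52, 0.52 and 0.51. This list's median was −0.086 after subtraction of the local background, and the list did not stand apart with the stricter filter on dim probes (17 genes, percentile 85.8) or with the median of a gene's probes (percentile 96.9). The 23 nonsense-mediated decay and splicing factor genes had a median of −0.17 (percentile 0.73), with HNRNPA1 (−0.77), TRA2A (−0.59), SRSF11 (−0.35) and SRSF10 (−0.30, other probes −0.04 and −0.13) lowest, and a median of 0.25 after that subtraction.

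In all, 12 of 22 further lists stood apart, 6 higher and 6 lower. Of 100 simulated lists without a shift 6 did so, a share that follows from the percentile limits themselves. It is no baseline for the fixed lists, whose genes are related and partly recur between lists. The 20 Wnt and beta-catenin targets did not stand apart (median 0.00, percentile 56.7), although APCDD1 (−2.21) and the Wnt antagonist gene DKK1 (−1.59) were at least 2-fold lower. With the stricter filter on dim probes, 12 of these targets had a median of −0.33, at percentile 0.05. The 29 intestinal differentiation genes lay just inside the random range (median −0.05, percentile 2.70) and stood apart as lower in 5 of 11 alternatives. Among them the trefoil factor gene TFF3 was lower (−1.08), but higher after subtraction of the local background (0.17). The 20 cholesterol and lipid synthesis genes (median −0.07, percentile 11.5), the 7 replication-dependent histone genes (−0.09, percentile 11.6) and the 22 housekeeping genes (−0.01, percentile 48.6) did not stand apart. The 60 cytosolic ribosomal protein genes had a median of 0.00 (percentile 63.4), but 0.19 (percentile 99.8) in the deposited value table, 0.18 (percentile 99.98) with scaling to a common median and 0.08 (percentile 99.0) with loess normalization.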

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

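The tests of array regions, normalization and admixed cells in this part were chosen after the result was seen. The test on neighbouring genes was written before its result was known, except for its value without the stretch of chromosome 2.

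Probes without a gene symbol were outside the comparisons. Of 2436 such probes above background, 8 were at least 2-fold higher on the CDR1AS array and 4 were at least 2-fold lower. The extremes were AHsV10002237 (log2 ratio 3.43) and opHsV0400000610 (−2.35).

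Interferon-stimulated genes were lower on the CDR1AS array (median −0.34). The values argue against normalization, offset or filter as the cause, since the highest percentile of the list over the alternatives was 0, and against a region of the array, since centring ratios within blocks left the median at −0.32. Leukocytes in the control culture stay open. Their markers had a median of −0.033, but only 2 of the 10 measured exceeded the background limit by a factor of 2 on the control array. These were CD79A (0.24) and LYZ (−0.09), neither of which fell as far as the interferon list's median. The others were near background on the control array, so little leukocyte signal was seen there, but no fall could be seen either. A difference between the cultures other than CDR1AS, such as unequal interferon signalling after lentiviral transduction, could give the same values and cannot be told apart from CDR1AS with 1 array per group.

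VIM by its brightest probe, AXL, TAGLN and FN1 were higher on the CDR1AS array, while 2 other VIM probes gave 0.02 and −0.07, and an effect of CDR1AS stays open. Fibroblasts in the culture are argued against by a fibroblast marker median of −0.055, with LUM at −0.34 and DCN at −0.07. A shift of a whole array block as the common cause is argued against because the 4 genes lay in 4 blocks and the lowest of their ratios within blocks was 1.09. Faults of single spots were not covered by this test. Cells of another line in place of SW620 were not excluded by the test fixed for them, in which medians over windows of 50 neighbouring genes spread 1.82 times as widely as with the gene order shuffled, and 1.51 times without 1 stretch of chromosome 2, between the bounds of 1.5 and 2 set for no and clear difference. The arrays nonetheless correlated at r = 0.984 across genes, with medians per chromosome between −0.04 and 0.045 and no other line to compare with.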

How the results depend on the processing

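Centring within array blocks and leaving out the genes of a shifted stretch of chromosome 2 were added after the data were seen. All other alternatives were planned. The count of genes past 2-fold, 126 higher and 96 lower, became 674 and 444 in the deposited value table, 229 and 172 with the smaller offset, 1932 and 1966 after subtraction of the local background, 435 and 372 at 1.5-fold and 36 and 24 at 3-fold. With the stricter filter, which kept 7398 of 16685 genes, 75 were higher and 65 lower. The value table differs from the main setting in background, offset and scaling at once, and the cause of its larger counts was not tested apart from the offset. Of the 222 genes past 2-fold, 221 were called in the same direction in the value table and 167 after local subtraction. The value table holds the same spot intensities without an offset, so its 221 calls are largely built in and are no independent check. Ratios correlated across genes with those of the main setting at r = 0.804 or more in all alternatives except local subtraction (r = 0.273), which moved the median of all genes to −0.10.

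Local subtraction gave 4 further lists standing apart in place of 12 and a ratio of 0.26 for LINC00632. It reversed the list medians of EGFR and MAPK output (−0.0019), p53 targets (−0.30), hypoxia and glycolysis (−0.086) and decay and splicing factors (0.25), turned that of S phase from −0.07 to 0.42 (percentile 99.6), and reversed the ratios of CCL20 (0.82), PHACTR3 (2.47) and TFF3 (0.17). The cause was not tested, but the rise of the local column at bright spots was a median of 68.6% of their intensity over blanks on the control array and 37.3% on the other. In 9 other alternatives, interferon, class I, oxidative phosphorylation, decay and splicing, G2 and M phase, stress response and MAPK lists kept their calls, NF-kB and p53 lists in 8, heat shock and hypoxia in 7 and the epithelial list in 4. Without the stretch of chromosome 2 the heat shock and epithelial lists lost their calls, leaving 10 of 12. The epithelial list has 0 members in the stretch and kept its median of −0.09. Only the random lists changed for it, which moved its percentile from 2.43 to 2.65, across the limit of 2.5. VIM had a ratio of 0.02 with the median of its probes.

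Signal close to background limits the dim genes, whose simulated changes were mostly missed. With 1 array per group leaving out an array was not possible. No paired analysis was possible because each group holds 1 array. The comparison by miR-7 sites in the 3' UTR was not run.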

Other observations

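The tests on chromosome 2 were chosen after the result was seen, and so were the genes and families named in this part. The test of NRF2 targets was written before its result was known.

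Metallothioneins, small cysteine-rich proteins that bind zinc and copper, were higher together on the CDR1AS array. All 10 measured members were above 0, with a median of 1.52 and 8 at least 2-fold higher, but after subtraction of the local background 9 were above 0 and 4 past 2-fold. The 10 members were taken by symbol, and the 8 include the pseudogenes MT1P3 (1.30) and MT2P1 (1.58). Near-identical family members can share labelled RNA, so the number of separate genes involved is uncertain. SLC30A1, a zinc exporter gene regulated by the same metal-responsive factor, had a log2 ratio of −0.26. The neuronal guidance genes CRMP1 (2.27) and DPYSL3 (1.73) were both at least 2-fold higher, but DPYSL3 had 0.76 after subtraction of the local background, and of the other measured members DPYSL4, above background on the CDR1AS array only, was at least 1.71-fold higher, while DPYSL2 and DPYSL5 had −0.02 and −0.14. Of 15 kallikrein genes, KLK10 (−2.23), KLK11 (−1.88) and KLK1 (−1.30) were at least 2-fold lower, but KLK11 had 0.65 after subtraction of the local background. CXCL6 (−1.88) was lower with CXCL8, CXCL3 and CXCL2, so that 4 of 10 measured CXCL chemokine genes were at least 2-fold lower (3 after subtraction of the local background).

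NQO1 (1.05), TXNRD1 (1.13), FTL (1.48) and AKR1C2 (1.81), targets of the oxidative stress factor NRF2, were at least 2-fold higher by their brightest probes. With the median of a gene's probes AKR1C2 had 0.97 and TXNRD1 0.58, and after subtraction of the local background TXNRD1 had −0.50. The hypothesis that NRF2 target genes in general were higher was tested on 22 other measured targets, of which 17 were above 0. Their median of 0.10 lay at percentile 98.8 of random lists, but at percentile 87.3 after subtraction of the local background. ME1 (0.84), UGDH (0.75) and GCLM (0.69) led, and PIR (−0.69) and PGD (−0.43) were opposite, but after that subtraction ME1 had −0.83, UGDH 0.12, GCLM 0.08, PGD 0.22 and FTL 0.92. The pattern may reflect a broader NRF2 response (percentile 98.8), and a difference between cultures unrelated to CDR1AS remains open. NFE2L2, which encodes NRF2, had a log2 ratio of 0.36 and lies in the stretch of chromosome 2 described next, as do members of fixed lists, namely HSPD1 and HSPE1 (heat shock), PDK1 (hypoxia), NDUFB3 and NDUFS1 (oxidative phosphorylation) and CLK1 (splicing).

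Of 100 neighbouring measured genes on chromosome 2, from GORASP2 to ZDBF2 in the gene order of GRCh38.p14, 88 were higher on the CDR1AS array, with a median log2 ratio of 0.36 (quartiles 0.11 and 0.50), and ITPRID2 (1.35) past 2-fold. After subtraction of the local background 64 were above 0, with a median of 0.32, 31 genes at least 2-fold higher, 5 at least 2-fold lower and ITPRID2 at −0.07. The highest window median over 1000 shuffles of the gene order was 0.17, about that of the next windows of the chromosome (FASTKD2 to ANKZF1 at 0.15 and STK16 to INPP5D at 0.17), so the ends of the shift are uncertain, but under that of the stretch, which argues against chance order, and the median within array blocks was 0.37 with probes in 23 of 24 blocks, which argues against a region of the array. In the deposited value table the median was 0.54, that is 1.46-fold, with 8 genes past 2-fold, 0.59 in the brighter part of the genes and 0.43 in the dimmer part, near the 0.585 of 3 copies against 2. A candidate explanation is a copy number difference between the cultures, as between subclones of SW620, which CDR1AS would not need to cause; DNA was not analysed here, and a shared regulatory change over the stretch remains open.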
